A study of Mus musculus with 2 samples.

How the data were processed

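The deposited files hold 1 single-cell library of RNA and 1 library of antibody tags (CITE-seq) from the same CD45-negative dura cells, pooled from 6 mice. Per the submitters' processing notes, reads were processed with Cell Ranger against the mouse build mm10; versions and settings are not stated. The deposited matrix gives raw counts, as UMI counts per gene and counts per antibody tag in each barcode (whole numbers of at least 1, checked on the values). The other deposited values are names and labels: feature names, barcodes, and the authors' cell type, cluster number, age and sex for each listed barcode. How the authors clustered, filtered and named the cells is not stated. No change of scale had been applied to the counts.

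The matrix held 7738 barcodes with 500 to 7938 gene UMIs each (median 1988) and 14 to 7356 antibody counts (median 268). Barcodes of the annotation were matched to the matrix by name: 6697 matched, 384 annotated cells were not in the matrix, and 1041 matrix barcodes had no annotation. Composition was computed over all 7081 annotated cells and everything else over the 6697 matched cells. No cell was removed beyond the authors' choice. Gene names that occur more than once (78) were told apart by identifier, and genes are named as in the deposited feature list. Lineage classes were made from the words of the deposited labels: fibroblast, endothelial, mural (pericytes), glial (labelled oligodendrocytes) and other; no label named an immune type. Types with under 50 cells are given as numbers of cells, except where a share of their cells is printed with its count.

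With 1 library per group there are no replicates, so no p-value was computed and cells were not used as replicates. Gene UMIs were summed per type, cluster or class and divided by all gene UMIs of that group (CPM). Intervals are exact: Garwood intervals for sums, Clopper-Pearson intervals for shares and conditional binomial intervals for ratios of 2 sums, all at 95% and for counting error only. A count of 0 allows a level of up to 3 counts, and a ratio against 0 counts is given only as a lower bound from 3 counts. In a comparison of clusters within a type, a gene met the size rule when its ratio was at least 2 with an interval clear of 2 (or 0.5) and both sums together held at least 50 UMIs; this is a rule on size, not a test. Each cluster was set against the other clusters of its type. List medians are of log2 ratios with 1 CPM added, and they were ranked among 10000 random lists matched on mean expression in 50 bins; the list ranks are descriptions. In fibroblasts the matched lists put the collagen, proteoglycan, remodelling, bone and cartilage and Wnt medians at percentile 100, the IGF median at 99.3, the TGF-beta and BMP median at 99.7 and the MHC class II median at 99.8. In their own classes the adhesion, basement membrane and immediate early medians of endothelial cells, the contractile median of mural cells, the myelin median of glial cells and the cell cycle median of the other class stood at 100.

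An antibody counted as above background in a type when its mean count per cell was at least 3 times that of the highest of 9 isotype controls with a named host. The tag IgG2a, with no host in its name, was in neither set. Protein and RNA pairs had been fixed by antibody and gene name; 115 antibodies matched a gene, and the 46 with at least 50 UMIs and at least 1 antibody count were used. For shares of cells with a UMI, each cell was also thinned to 500 UMIs (seed 1), which kept all 6697 cells. Marker lists of other cell types, leukocytes, erythroid cells and pinealocytes among them, were fixed with the function lists.

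The comparisons, the gene lists, the pairs, the alternatives and the rule for named genes were set before the data were examined. The rule names, per list, at most the 4 genes with the highest CPM in the class where the list is highest; per class and per cluster, the 5 genes with the largest ratio among those with at least 50 UMIs and a UMI in at least 10% of the cells; per type, the 3 antibodies with the largest ratio among those above background; the discordant pairs above background, at most 10; and Ptprc, Xist and the mitochondrial share. For the ranking of genes, fewer than 3 UMIs on the other side were counted as 3, so the order can differ from that of the printed ratios. Genes named outside the rule are marked as chosen after their values were seen.

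The size rule was tried on simulated counts with 200 genes changed, drawn with counting error alone around the pooled levels of these cells. The intervals assume the same error, and spread between cells was left out, so few false calls were built in. The false calls below therefore do not measure those in the real data. In fibroblast cluster 1 against the other fibroblast clusters (10689 genes) it recovered 75% of genes changed 3-fold, 88% at 4-fold and 94.5% at 8-fold, with 0 false calls. In endothelial cluster 13 (3481 genes) it recovered 35%, 60% and 81.5%, with 0 false calls. In proliferating erythrocytes (443 genes) it recovered 34%, 68.5% and 86.5%, with 1 false call at 3-fold. The rule for the highest class recovered, at 8-fold, 100% of genes in fibroblasts, 98.5% in endothelial cells, 78.5% in mural cells, 97% in glial cells and 99% in the other class, with at most 11 false calls among 2828 unchanged genes. Of 200 random lists of 13 genes, 6.6% of ranks fell outside the central 95%, and lists raised 4-fold all stood at percentile 100.

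Alternatives were a quality filter (at least 1000 UMIs and under 10% mitochondrial UMIs), doublet removal with Scrublet, scaling without mitochondrial, ribosomal protein and the 20 most abundant genes, the mean of each cell's own CPM, thinning, minimums of 200 UMIs and none, intervals clear of 1.5 and 4, isotype multiples of 2 and 5, centred log-ratios, shares of antibody counts, only antibodies above background, and own clusters (Leiden, 2000 variable genes, 30 principal components, 15 neighbours, resolutions 0.5 and 1, seed 0). Scrublet's automatic threshold of 0.601 marked 0 of 7738 barcodes, so that removal could not be run as planned and doublets were not removed. Added after the data were seen were: leaving out the 5% of barcodes with the highest Scrublet scores (363 annotated cells), leaving out endothelial cluster 7, counting composition over matched cells only, counting IgG2a as an isotype control, and keeping erythroid, ependymal and epithelial cells apart. Own clusters were named from the fixed markers by a rule that was changed after its first output, which had called fibroblast clusters of 705 and 304 cells neutrophils: a marker now counts only with a UMI in at least 10% of the cluster's cells, and 3 such markers are needed. The own clusters numbered 17 and 22, and 99.0% of cells kept the class of the annotation at both resolutions. Several marker lists share 1 class, so this share does not test the labels within a class. The own cluster with the labelled oligodendrocytes was named Schwann and that with the pericytes smooth muscle. Of clusters made up of cells labelled fibroblasts, 1 of 245 cells was named osteogenic. Another, of 980 cells at resolution 0.5, was named arachnoid and dural border cell, and 1 of 708 cells at resolution 1 was named chondrogenic.

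Matrix barcodes without annotation were left out of all comparisons except the test of free RNA in endothelial cluster 7, and are described on their own. The genome sequence was not used here. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.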

Results

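The non-immune cells of the mouse dura mater, the outer membrane around the brain, were profiled for RNA and surface protein in the same cells. Dura of 6 wild-type mice, 12 weeks old and listed as female, had been pooled, and cells lacking CD45, the pan-leukocyte surface protein, had been taken. The group measured for RNA and the group measured for antibody tags each held 1 library (n = 1), so no difference carries a replicate error or a test, and every interval covers counting error only, at the 95% level. The RNA library held 16357080 unique molecular identifiers (UMIs, each counted as 1 RNA molecule) of 32285 genes in 7738 barcodes, and the antibody library held 3927529 counts of 168 tags in the same barcodes. The deposited annotation named 7081 cells in 9 types and 19 clusters, and 6697 of those cells were in the count matrix, with 15365591 gene UMIs and 3644273 antibody counts. A median annotated cell had 2187 UMIs, 1104 genes, 4.94% mitochondrial UMIs and 283 antibody counts. Xist, the RNA of the inactive X chromosome of females, gave UMIs in 5127 cells (76.6%), and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d gave 0 UMIs.

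Which cells make up the CD45-negative dura was the question of the cell type composition. Fibroblasts, the matrix-producing cells of connective tissue, were 5299 of the 7081 annotated cells, or 74.8% (exact Clopper-Pearson interval 73.8 to 75.8). Endothelial cells, which line blood and lymph vessels, were 1117 cells, or 15.8% (14.9 to 16.6). The remaining types were small: 206 erythrocytes (2.91%), 113 cells labelled ependymal (1.60%), 96 labelled oligodendrocytes (1.36%), 87 proliferating erythrocytes (1.23%), 71 epithelial cells (1.0%), 63 pericytes (0.890%) and 29 cells labelled habenulal neuroblast-like (0.410%). The fibroblasts fell into 8 clusters, of which cluster 1 was the largest with 1228 cells (23.2% of the fibroblasts), and the endothelial cells into 4, of which cluster 6 was the largest with 555 cells (49.7%). Of the annotated cells, 384 were missing from the matrix, among them 306 endothelial cells, 243 of these from endothelial cluster 7, and 36 of the cells labelled oligodendrocytes. The share of the class glial, which holds the labelled oligodendrocytes alone, was 1.36% (1.1 to 1.65) in the annotation and 0.896% of the annotated cells in the matrix, a count added after the data were seen. Among cells with at least 1000 UMIs and under 10% mitochondrial UMIs, endothelial cells made up 7.62%, mural cells (the pericytes) 0.558% and glial cells 0.209%.

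**Figure D1:**
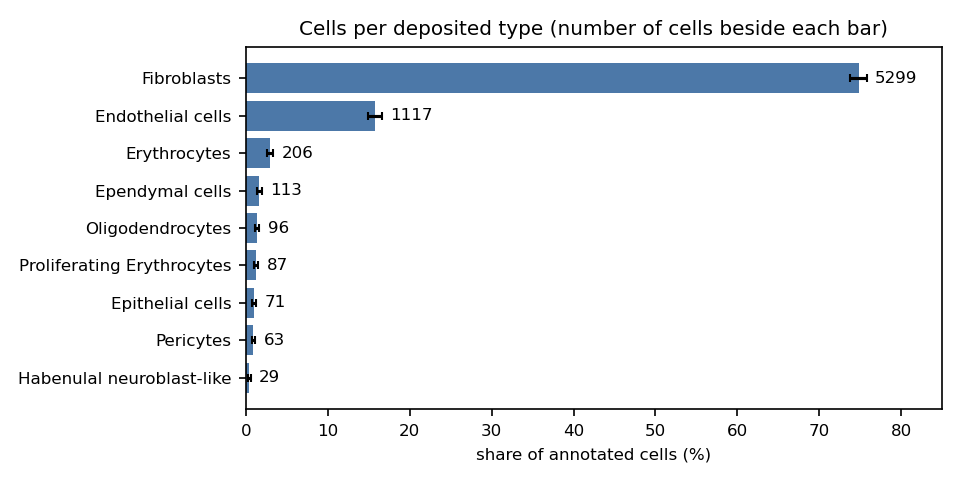
Share of the 7081 annotated cells in each deposited cell type, in percent, with the number of cells beside each bar; error bars are exact 95% binomial intervals (counting error only, 1 library). Fibroblasts held 74.8% of the cells and endothelial cells 15.8%.

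Gene lists fixed in advance were then compared between the lineage classes fibroblast, endothelial, mural, glial and other (erythroid, ependymal, epithelial and neuroblast-like cells). By list median, the collagen, proteoglycan and matrix remodelling lists stood highest in fibroblasts, the leukocyte adhesion and MHC class I lists in endothelial cells, the contractile list in mural cells and the myelin list in glial cells. The basement membrane list was lower in fibroblasts than in all other cells, with a median ratio of 0.522. For fibroblasts, all other cells include 582650 UMIs of erythrocytes, which are mostly haemoglobin, beside 1023361 of endothelial cells. Haemoglobin lowers the CPM of other genes there and so raises the fibroblast ratios of the lists. Random lists matched on expression carry this shift too: the angiogenic list, at a median ratio of 1.44 in fibroblasts, stood at percentile 54.9 among them. Of 316 listed genes in 25 lists, 312 had a UMI. A gene was called highest in a class when the lower bound of its CPM (UMIs of the gene scaled to a fixed total of all gene UMIs) there exceeded the upper bound in each other class. By that rule 40 genes were highest in fibroblasts, 24 in endothelial cells, 24 in mural cells, 19 in glial cells and 4 in the other class. For 205 genes no class stood clear of the rest.

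In fibroblasts, the median collagen gene of the fibrillar list was 8.63 times its level in all other cells, with 4 of 13 members highest there, 2 highest in mural cells and 1 in glial cells. Col1a2 and Col1a1, the chains of type I collagen, reached 2322 CPM (2296 to 2348) and 1537 CPM (1515 to 1558) in fibroblasts against 771 and 614 in mural cells and 250.2 and 182 in endothelial cells. Col3a1, of type III collagen, was higher in mural cells, at 1738 CPM (1455 to 2059), than in fibroblasts, at 743 (728 to 758). Of 17 genes for small proteoglycans and matrix glycoproteins, 8 were highest in fibroblasts, with a list median ratio of 5.34; decorin (Dcn) reached 3652 CPM and osteoglycin (Ogn) 1597 CPM, while Sparc was higher in glial cells (5259 CPM) than in fibroblasts (3416 CPM). The calcification inhibitor Mgp was the most abundant gene of that list, at 26061 CPM in fibroblasts and 20762 CPM in mural cells. The bone and cartilage list had a median ratio of 10.4 and 4 of 12 detected genes highest in fibroblasts, among them chondroadherin (Chad, 554 CPM), the cartilage matrix gene Comp (527 CPM), the phosphatase gene Alpl (490.2 CPM) and osteopontin (Spp1, 303 CPM). Chad and Spp1 were carried mainly by single fibroblast clusters, Chad at 2554 CPM in cluster 2 against 147 in the other fibroblasts and Spp1 by cluster 8. The own clusters named 245 cells, all labelled fibroblasts, osteogenic at both resolutions. At resolution 1 alone they named a further 708 cells, all labelled fibroblasts, chondrogenic. The fibroblast values here include these cells. Matrix remodelling enzymes had a median ratio of 5.74 (3 of 13 highest in fibroblasts), with the protease inhibitor gene Timp2 at 1074 CPM.

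Of 7 lists of secreted signals, 3 had a median ratio over 2 in fibroblasts, and the neurotrophic list stood at 0.653. The insulin-like growth factor list had a median ratio of 5.30, with 4 of 8 genes highest in fibroblasts; Igfbp5 reached 8630 CPM and Igf2 1125 CPM, whereas Igfbp7 was higher in mural cells, at 3985 CPM, than in fibroblasts, at 1320 CPM. The Wnt list had a median ratio of 3.33 (3 of 16 highest in fibroblasts), with the Wnt amplifier Rspo3 at 579 CPM against 54.7 in endothelial cells. The TGF-beta and BMP list had a median ratio of 2.26 and 1 of 14 genes highest in fibroblasts, Gdf10 standing at 638 CPM against 169.9 in mural cells. The cytokine Il33, an alarmin, reached 217 CPM in fibroblasts and 28.3 CPM in endothelial cells, in a list of leukocyte growth and survival cytokines with 1 of 13 detected genes highest in fibroblasts and 1 in mural cells. Among 16 chemokine genes, Cxcl12 was highest in mural cells (1529 CPM, against 543 in endothelial cells and 259 in fibroblasts).

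In endothelial cells, the median leukocyte adhesion gene was 19.6 times its level in all other cells, and 6 of 13 detected members were highest there. Pecam1 (CD31) reached 1011 CPM (951 to 1075), against 52.3 in mural cells and 3.94 in fibroblasts, Icam2 361 CPM and Cd34 523 CPM. MHC class I genes, which present peptides to CD8 T cells, had a median ratio of 2.82 with 2 of 7 highest in endothelial cells; H2-D1 stood at 1646 CPM, B2m at 1524 CPM and H2-K1 at 1400.3 CPM, against 453, 675 and 253 in fibroblasts. Immediate early genes, which also respond to tissue dissociation, had median ratios of 7.68 in endothelial and 4.40 in mural cells and 0.252 in fibroblasts; Jun reached 419 CPM in endothelial cells and 63.9 in fibroblasts. The basement membrane list had median ratios of 2.75 in endothelial, 2.09 in mural and 2.24 in glial cells, and Col4a1, a chain of type IV collagen, stood at 1058 CPM in endothelial and 1071 CPM in mural cells. Among 16 barrier transporter genes, 4 were highest in endothelial cells, with the glucose transporter Slc2a1 at 348 CPM against 3.94 in fibroblasts and Slco1a4 at 152 CPM against 0.619.

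Mural cells had 10 of 11 contractile genes highest, with a median ratio of 41.0; the smooth muscle genes Tagln and Acta2 stood at 4860.5 CPM (4379 to 5380) and 4272 CPM (3822 to 4762), against 134 and 122 in fibroblasts. The cells labelled oligodendrocytes had 7 of 11 Schwann and myelin genes highest, with a median ratio of 73.8. Mog, Mobp and Olig2, markers of central oligodendrocytes chosen here after their values were seen, had 0 UMIs in these cells, which allows up to 54.6 CPM each (3 counts). The cell cycle list was highest in the other class, with a median ratio of 31.9 and 3 of 12 genes highest; Mki67 reached 272 CPM there and 0.309 CPM in fibroblasts. With erythroid, ependymal and epithelial cells kept apart, a split added after the data were seen, 4 cell cycle genes were highest in erythroid cells, and the endothelial counts fell to 5 adhesion genes and 3 barrier transporters and the mural count to 9 contractile genes.

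The MHC class II list, whose products present peptides to CD4 T cells, had a median ratio of 2.82 in fibroblasts over all other cells. Of its 7 genes, 0 stood clear of every class, and Cd74 was at 79.8 CPM in fibroblasts and 89.9 CPM in endothelial cells. Fibroblast cluster 1 carried most of the fibroblast level, at 625 CPM for 4 of these genes together against 68.0 in the other fibroblasts. Complement genes had a median ratio of 1.83 in fibroblasts and 0 of 13 highest there, with the C1 inhibitor gene Serping1 at 537 CPM. In mural cells 2 complement genes were highest, and in glial cells 2. The heat shock list had 0 of 9 genes highest in any class, and 1 in epithelial cells after the split. Junction genes divided, with 3 of 15 highest in fibroblasts and 3 in endothelial cells, and the cadherin gene Cdh11 stood at 1045 CPM in fibroblasts. Of the retinoid and prostaglandin genes, 3 of 14 were highest in fibroblasts, 1 in endothelial cells and 1 in the other class; with the other class split as above, 1 was highest in fibroblasts, 1 in endothelial, 1 in ependymal and 2 in epithelial cells. Angiogenic and mural signals had 3 of 15 genes highest in mural cells, 2 in endothelial cells and 1 in fibroblasts, and the pericyte attractant Pdgfb stood at 204 CPM in endothelial cells and 0.696 CPM in fibroblasts. The interferon list had 1 of 10 genes highest in each of endothelial, mural and glial cells, and the neurotrophic list 2 of 13 in glial cells and 1 in fibroblasts; after the split, glial cells kept 0 interferon genes and 1 neurotrophic gene, and erythroid and epithelial cells had 1 interferon gene each. The counts of highest genes depended on depth: with every cell thinned to 500 UMIs they were 26 in fibroblasts, 15 in endothelial cells, 11 in glial cells and 2 in the other class. The stricter quality filter, which also leaves out cells, gave 23, 13, 13 and 2, with 14 in mural cells. Scaling without the most abundant genes gave 12 in the other class in place of 4.

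**Figure D2:**
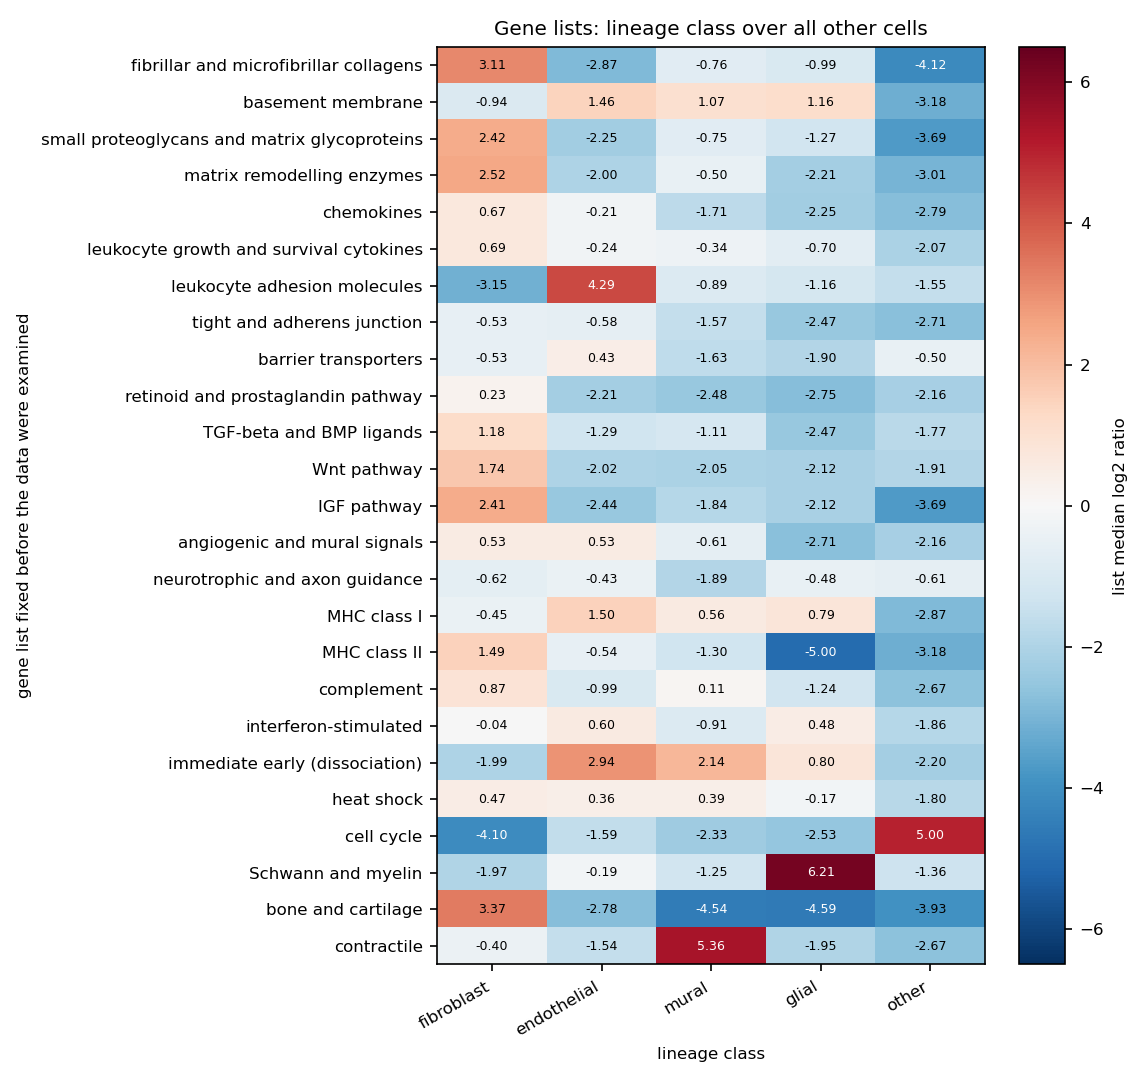
Median log2 ratio of CPM (1 CPM added to both sides) of each fixed gene list, lineage class over all other annotated cells; red is higher and blue lower in the class. Members with 0 UMIs in a class pull its blue values by an amount set by the added 1 CPM. Contractile genes stood at 5.36 in mural cells, Schwann and myelin genes at 6.21 in glial cells, leukocyte adhesion genes at 4.29 in endothelial cells and fibrillar collagens at 3.11 in fibroblasts.

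The genes with the largest ratio per class describe the annotation, whose making is not stated and may have used the same RNA; they are not counted as independent findings. In fibroblasts they were Nppc, Myoc, Trabd2b, Cybrd1 and Col8a2, at 12.4 to 21.0 times the next class. In endothelial cells they were Myct1, Tmem252, Stab1, Lrg1 and Grrp1; Myct1 (ENSMUSG00000046916) reached 235 CPM, 234 times the level in fibroblasts (134 to 446). In mural cells Myh11, the smooth muscle myosin, stood at 915 CPM, 156 times the endothelial level (68.2 to 439.5), followed by Mustn1, Acta2, Tagln and Abcc9. In the labelled oligodendrocytes the leading genes included Gfra3, the potassium channel genes Kcna2 and Kcna1 and the sodium channel gene Scn7a. In the other class the leading genes were Rhd, Mki67, Tspo2, Hemgn and Trim10. Among its types, the epithelial cells were marked by Ttr, the transthyretin gene of the choroid plexus, at 270515 CPM, 2400.4 times its level in all other annotated cells (2287 to 2521). The erythrocytes were marked by the haemoglobin gene Hbb-bs at 496871 CPM, and the cells labelled ependymal by Gm20383, Jhy, Pax6, C130073E24Rik and Cspg5.

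Fibroblast clusters were compared with each other to ask how the fibroblasts of the dura divide. Cluster 1 was marked by Ccn3 (ENSMUSG00000037362), a secreted matricellular protein, at 792 CPM, 41.1 times its level in the other fibroblast clusters (35.4 to 48.0), and by Mal2, Penk, Tnfrsf11b and Slc16a11. Cluster 8 carried bone matrix genes: Ibsp, encoding bone sialoprotein, was 716 times higher (447 to 1219) and Bglap, encoding osteocalcin, 299.7 times higher (213 to 433), with Tnc, Mmp13 and Bglap2 next. Cluster 12 carried interferon-induced genes, with the chemokine gene Cxcl10 311 times higher (197 to 517), Rsad2 136 times and Ifit1 49.9 times, followed by Iigp1 and Ifit3b. Cluster 5 was marked by Pi16, 77.9 times higher (56.1 to 111), with Clec3b, Ebf2, Edn3 and Prss35.

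The remaining fibroblast clusters were set apart by smaller ratios, except cluster 18. Cluster 2 had Mmp9, a gelatinase, at 26.0 times, then Gpha2, Chad at 17.4 times, Dio2 and Scara5. Cluster 3 had Nppc at 5.76 times, then Col6a5, Cxcl14, Npy1r and Angpt4, and cluster 4 had Pappa2 at 20.2 times, then Pappa, Dner, Fndc5 and Lbx2. Cluster 18, with 61 cells, had Moxd1 at 537 times (321 to 953), then Coch, the cystine transporter gene Slc7a11 at 94.0 times, Lsamp and Emcn. Many leading genes gave UMIs in a minority of the cells of their cluster: Pappa2 in 10.6%, Mmp9 in 13.1%, Ibsp in 14.0%, Cxcl10 in 18.3% and Pi16 in 22.1%, while Moxd1 did in 49.2% and Ccn3 in 54.4%.

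By fixed list, and by a size rule on summed UMIs that is not a test (a ratio of at least 2 with an interval clear of 2), the clusters differed in the listed genes. Cluster 8 had 7 of 12 detected bone and cartilage genes and 7 of 13 fibrillar collagens higher than the other fibroblasts, with Spp1 163 times (149.5 to 178) and Col1a1 2.97 times. Cluster 12 had 9 of 10 interferon-stimulated genes and 4 of 7 MHC class I genes higher; H2-K1 was 2.88 times higher (2.49 to 3.31) and the list member Isg15, named after its value was seen, 33.5 times. Cluster 5 had 8 of 13 complement genes and 5 of 16 chemokine genes higher, with Cxcl12 at 4.30 times and, named after their values were seen, C3 at 33.2 times and Ccl11 at 276 times (74.2 to 2314). Cluster 1 had 5 of 7 MHC class II genes, 5 of 16 barrier transporters and 4 of 15 junction genes higher, with Cd74 10.3 times (8.88 to 11.9), the efflux transporter Abcg2 3.72 times and the connexin gene Gja1 7.80 times. Cluster 2 had 4 of 17 proteoglycan and glycoprotein genes higher, and of the bone and cartilage genes 3 were higher, with Comp at 5.76 times, and 3 lower. Cluster 18 had 4 of 16 Wnt genes higher and 1 lower. Cluster 3 had 1 chemokine gene higher and 5 lower, and cluster 4 had 2 bone and cartilage genes higher and 5 lower. In the lists named so far for clusters 1, 5, 8 and 12, at most 1 gene per list was lower. Other lists were lower: in cluster 1, 8 of 17 proteoglycan, 7 of 13 complement and 7 of 11 contractile genes, in cluster 2, 5 of 7 MHC class II genes, in cluster 4, 6 complement genes and in cluster 5, 7 bone and cartilage genes. Over all genes cluster 1 had 245 higher and 460 lower. In all, 1450 genes met the size rule in at least 1 of the 8 comparisons; with the interval clear of 1.5 the number was 2317, clear of 4 it was 602, and with a minimum of 200 UMIs 918.

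Endothelial clusters were compared in the same way. Cluster 13 had 4 of 16 barrier transporters and 2 of 15 junction genes higher. The amino acid transporter gene Slc38a5 led at 206 times its level in the other endothelial clusters (54.9 to 1736, on 2 UMIs there), the glucose transporter gene Slc2a1 stood at 2269.7 CPM, 86.5 times higher (56.7 to 138), then came Mal, Ptgs2 and Tmem252, and Slco1a4 was 19.9 times and Abcb1a 7.24 times higher. Cluster 10 was marked by Ccl21a, a chemokine gene of lymphatic endothelium, 104 times higher (59.9 to 196) with UMIs in 12.8% of its 141 cells, then Mmrn1 (in 15.6% of them), F8 and Gpm6a. As Ccl21a and Mmrn1 gave UMIs in a minority of its cells, they do not name the whole cluster lymphatic. Own clusters named 19 endothelial cells lymphatic at both resolutions, and in which deposited clusters these lay was not computed. Cluster 6 was marked by Esm1 at 87.9 times (29.8 to 428, on 3 UMIs in the other clusters), Igfbp3 at 38.3 times, Rbp7, Ramp3 and Btnl9, and had 3 of 13 basement membrane genes higher, Col4a1 among them at 4.62 times (3.89 to 5.53). Cluster 7 had Hbb-bs, S100a6, Vim, S100a11 and the tight junction gene Cldn5 leading, the last at 2.13 times; of its haemoglobin UMIs 97.9% came from 1 of the 72 cells in the matrix, and without that cell haemoglobin stood at 599.8 CPM against 386 in the other endothelial clusters. In cluster 13, 11 of 12 immediate early genes were also higher, Jun by 4.71 times (3.87 to 5.72) and Ier3 by 19.7 times. In all, 327 genes met the size rule; the number was 531 with the interval clear of 1.5, 118 clear of 4, 122 with a minimum of 200 UMIs and 665 with none.

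Proliferating erythrocytes were compared with erythrocytes. The leading gene, Hmgb2, stood at 2335 CPM in the former and at 1 UMI in the latter, a ratio of 1360.5 (243 to 53821), followed by Anp32b, Hist1h1b, Mki67 and Dek, and 7 of 12 cell cycle genes met the size rule. Of the 356 genes that met it, 355 were higher in the proliferating cells (99.7%). Haemoglobin filled most of the UMIs of the erythrocytes, and with the most abundant genes left out of the scaling 193 genes met the rule, 64.2% of them higher in the proliferating cells. With a minimum of 200 UMIs 78 genes met it, and with none 2115.

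Surface protein was measured by antibody tags in the same cells; whether the authors used the tags to define the types is not stated. Of 158 antibodies, 52 stood at 3 or more times the highest of 9 isotype controls (antibodies with no target, which measure unspecific binding) in at least 1 type. Endothelial cells were marked by CD31, the junctional adhesion protein, with 759 counts per cell (757 to 761), 66.4 times the mean of all other cells, and by the panendothelial antigen (64.9 times) and CD102 (58.2 times). Fibroblasts were marked by CD140a, the PDGF receptor alpha, with 4.30 counts per cell, 6.07 times the mean elsewhere (5.69 to 6.48), then CD80 and CD11b. Erythrocytes were marked by the red cell antigen TER119 (5.22 counts per cell, 34.8 times), the transferrin receptor CD71 (92.2 counts, 27.3 times) and CD24 (93.1 counts, 17.2 times).

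The leading antibodies of the smaller types were not all specific to them: CD9, CD106, CD71 and CD24 each led in 2 types. Proliferating erythrocytes had CD71 at 133 counts per cell (30.1 times), CD49d at 1.15 (29.7 times) and CD24 at 116 (17.4 times). The labelled oligodendrocytes had P2X7R, an ATP-gated channel, at 5.78 counts per cell (25.1 times), the laminin receptor subunit CD49f at 182 (5.84 times) and CD9 at 478 (5.68 times). Epithelial cells had the complement inhibitor CD55 at 126 counts (27.4 times), CD9 at 522 (6.30 times) and CD106 at 3.39. Pericytes had CD49a at 14.8 counts (5.79 times), ESAM at 17.9 and CD39 at 29.3, both higher in endothelial cells (30.3 and 75.3), beside the endothelial antibodies CD31 at 159 and CD102 at 14.3, and the cells labelled ependymal had CD272 at 2.82 (49.5 times), CD117 at 13.3 (21.0 times) and CD106 at 4.76. Among types with at least 50 cells, median antibody counts per cell ran from 243 in fibroblasts to 1595 in endothelial cells. The numbers of antibodies above background were 33 in fibroblasts, 26 in endothelial cells, 29 in mural, 24 in glial and 32 in the other cells. A further tag named IgG2a bound at 1.28 counts per cell in fibroblasts and 6.68 in endothelial cells; counted as an isotype control after the data were seen, it lowered these numbers to 13, 12, 15, 5 and 10 and put CD80 and CD11b of fibroblasts, CD272 of ependymal, CD106 of epithelial, P2X7R of glial and CD49d of proliferating cells within background; centred log-ratios gave 9, 21, 15, 13 and 9.

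**Figure D3:**
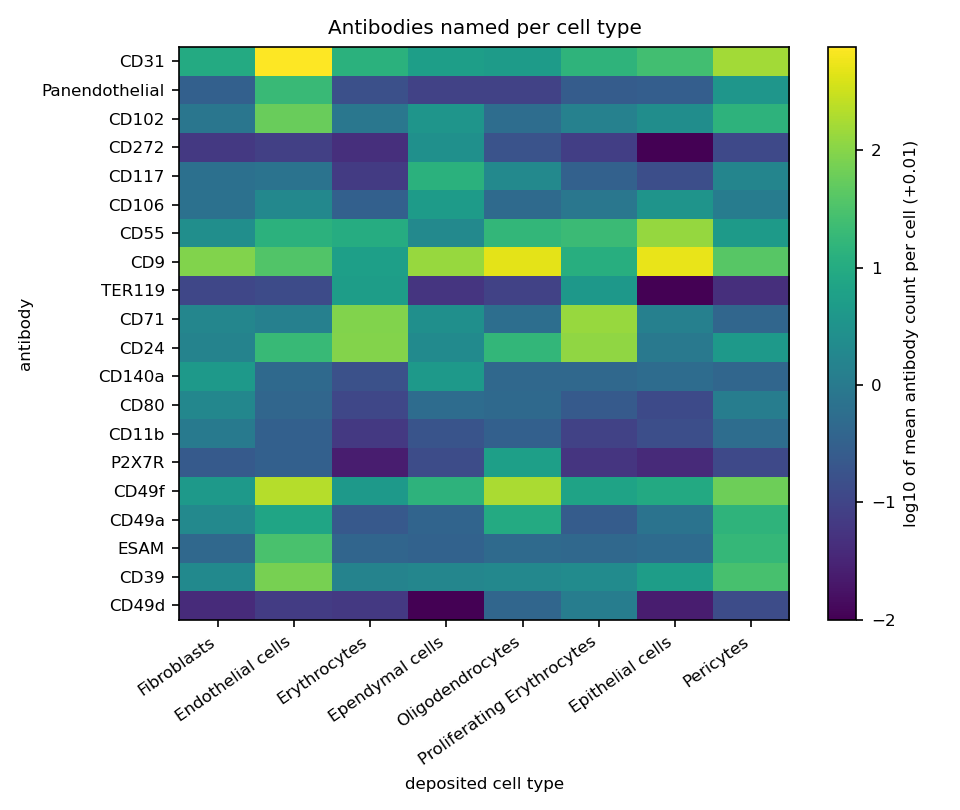
Mean antibody count per cell (log10 scale, 0.01 added) of the 3 leading antibodies of each deposited cell type with at least 50 cells, all types side by side. CD31 reached 759 counts per cell in endothelial cells, and CD71 92.2 in erythrocytes and 133 in proliferating erythrocytes. Levels of different antibodies are not comparable.

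Within fibroblasts and endothelial cells antibody levels differed between the deposited clusters as well; here they are ranked against the other clusters of the same type, a ranking chosen after the values were seen. Fibroblast cluster 18 carried 208 counts per cell of CD38, 45.0 times the other fibroblasts (44.1 to 46.0), and 14.4 of CD106, the adhesion protein VCAM-1, 29.1 times (26.9 to 31.4). Cluster 8 had the antigen-presenting protein CD1d at 4.42 counts, 10.7 times the other fibroblasts, and CD90.2 at 64.4 counts, 4.37 times, while cluster 2 had CD9 at 262 counts, 5.47 times, and CD90.2 at 47.4 counts, 5.02 times. Cluster 12, with the interferon genes, had the interferon-induced protein CD317 at 2.73 counts, 3.94 times the other fibroblasts (3.49 to 4.44), and the checkpoint ligand CD274 at 6.74 counts, 3.30 times (3.06 to 3.56). Cluster 1 had the costimulatory ligand CD80 at 4.09 counts, 3.76 times (3.61 to 3.92), and I-A/I-E, the MHC class II protein, at 4.14 counts, 1.88 times (1.82 to 1.95). The largest such ratios were 1.60 in cluster 3 (CD201), 1.62 in cluster 4 (CD31) and 2.89 in cluster 5 (Ly-6A/E). Among endothelial cells, cluster 13 had Ly-6A/E at 604 counts, 8.08 times the other clusters (7.99 to 8.18), cluster 6 had CD24 at 29.8 counts, 11.7 times, cluster 10 had CD55 at 50.7 counts, 8.47 times, and cluster 7 had CD63 at 6.03 counts, 5.97 times. Of these, CD1d in cluster 8, CD317 in cluster 12, CD63 in cluster 7 and CD201 in cluster 3 stood under 3 times the IgG2a tag, which gave 1.70, 1.12, 6.42 and 1.16 counts per cell there.

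Whether protein and RNA pointed to the same cell type was asked for the 115 antibodies with a matched gene, of which 46 had at least 50 UMIs and were used. Both measures were highest in the same type for 31 pairs, by the largest value alone, with no interval and no minimum count per type. Reshuffling genes among antibodies 10000 times gave 14.0 on average and at most 25. Some of the 31 rest on few counts: in epithelial cells Cd55 stood at 38.4 CPM and Nt5e, paired with CD73, at 12.8 CPM. MERTK protein stood at 0.0167 counts per cell in the labelled oligodendrocytes. CD31 and Pecam1, CD102 and Icam2, CD105 and Eng (endoglin), and ESAM and Esam were all highest in endothelial cells, CD140a and Pdgfra in fibroblasts, CD29 and Itgb1 in pericytes, CD71 and Tfrc in proliferating erythrocytes, and CD55 and Cd55 in epithelial cells; these examples were chosen after the values were seen. Of the 33 pairs with the protein above background, 24 had the same top type and 9 differed. CD9 protein was highest in epithelial cells (522 counts per cell) and its RNA in the labelled oligodendrocytes (2602 CPM, against 301 in epithelial cells). CD106 protein was highest in the cells labelled ependymal and Vcam1 RNA in endothelial cells, and CD304 protein in pericytes and Nrp1 RNA in endothelial cells. Among the other differing pairs were CD49d with Itga4, CD63 with Cd63, CD90.2 with Thy1, CD172a with Sirpa and CD95 with Fas. Antibodies above background whose gene gave under 50 UMIs were left out of these pairs. They include the leading antibodies CD80 (36 UMIs of Cd80), CD11b (3 of Itgam), CD272 (6 of Btla), CD117 (24 of Kit) and P2X7R (31 of P2rx7). With no gene minimum, 45 of 93 pairs had the same top type. With antibodies scaled to the share of all antibody counts of a type, only 14 of the 46 pairs had the same top type. That is no more than the reshuffled mean of 14.0 for the unscaled counts, and no reshuffling was run for the scaled ones. The number of 31 pairs therefore depends on leaving the antibody total of each type unscaled.

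MHC class II was then followed within the fibroblasts, a comparison chosen after the values were seen. In cluster 1, 32.8% of 1227 cells held a UMI of Cd74, H2-Aa, H2-Ab1 or H2-Eb1, against 7.92% of the other fibroblasts. With every cell thinned to 500 UMIs the share was 17.0% in cluster 1 and 0.930% to 8.26% in the other fibroblast clusters. In erythrocytes, which should lack these genes, 2 of 200 cells held a UMI of the 4 (6 UMIs together), at median depths of 2869.5 UMIs in erythrocytes and 2471 in cluster 1. Summed, the 4 genes reached 625 CPM in cluster 1 (598 to 653) and 68.0 CPM in the other fibroblasts, a ratio of 9.19 (8.41 to 10.0). Protein and RNA were found in the same cells: in cluster 1 the I-A/I-E antibody gave 10.5 counts per cell in the 403 cells with a UMI of these genes and 1.05 in the 824 cells without, a ratio of 9.92 (9.22 to 10.7), while the isotype controls together gave 0.702 and 0.659. Median depths of these cells were 2634 and 2395.5 UMIs. In fibroblast cluster 5 the I-A/I-E antibody gave 7.92 counts per cell with a UMI and 2.30 without, and in cluster 3 it gave 9.65 and 1.94.

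**Figure D4:**
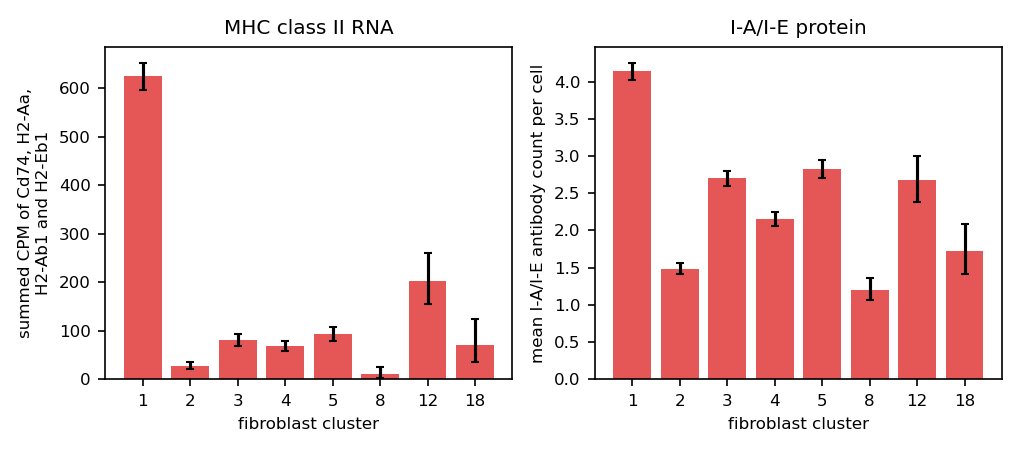
Left, summed CPM of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 per fibroblast cluster; right, mean I-A/I-E antibody count per cell in the same clusters. Error bars are exact 95% Poisson intervals (counting error only, 1 library). Cluster 1 stood highest in both, at 625 CPM and 4.14 counts per cell.

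The removal of CD45-positive cells was checked with Ptprc, the gene of CD45. A Ptprc UMI was found in 2 of 6697 annotated cells, or 0.0299% (0.00362 to 0.108), and thinning each cell to 500 UMIs left the same share. Both cells were in endothelial cluster 7 and held 8 Ptprc UMIs together, and the same 2 cells held all 558 UMIs of S100a8 and S100a9 in that cluster, neutrophil genes chosen after their values were seen. Fibroblasts, which should lack the gene, had 0 of 5279 cells with a Ptprc UMI, which allows a share of up to 0.0568% of cells with a UMI (3 counts) and does not limit cells expressing the gene, at a median of 2319 UMIs against 1042 in endothelial cells. Of 7 pan-leukocyte genes, at least 1 gave a UMI in 1822 cells (27.2%), nearly all of them through Srgn, which gave UMIs in 24.6% of fibroblasts and 54.5% of endothelial cells. Without Srgn, left out after the data were seen, 89 cells (1.33%) held a UMI of the other 6 genes, 1.23% of fibroblasts and 2.84% of endothelial cells. No antibody tag for all forms of CD45 was used here.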

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

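The tests of free leukocyte RNA and unspecific binding in fibroblast cluster 1, and of free RNA in endothelial cluster 7 were chosen only after the results were seen. Matrix barcodes without annotation, used only in that last test, held RNA and antibody signal above the limit that a count of 0 allows: Hbb-bs at 60190 CPM against 24595 CPM in annotated cells, Ttr at 5135 CPM against 2863 CPM, and the epithelial antibody CD326 at 1.13 counts per barcode against 0.200 in annotated cells. Of the CD326 counts in these 1041 barcodes, 56.2% came from 1 barcode. These barcodes had a median of 827 UMIs and 11.2% mitochondrial UMIs, and 71 of them held mostly haemoglobin UMIs.

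MHC class II RNA and the I-A/I-E antibody stood higher in fibroblast cluster 1 than in the other fibroblasts. Leukocytes or leukocyte doublets as the source in most of these cells are argued against. Of its 403 cells with an MHC class II UMI, 7 (1.74%, 0.701 to 3.55) held a UMI of Ptprc, Coro1a, Laptm5, Tyrobp, Fcer1g or Cd52, where that source would need most of them to. Among its cells without an MHC class II UMI the share was 0.728%. The 12 cells with the most held 20.5% of the class II UMIs, with up to 76 in 1 cell. For so few cells, the share over all 403 cannot exclude leukocytes. Free leukocyte RNA would spread over all fibroblasts, and the summed CPM was 9.19 times higher in the cluster (8.41 to 10.0). That ratio is the pattern itself, so its test could not have come out otherwise. Apart from it, 2 of 200 erythrocytes (1%, 0.121 to 3.57) held an MHC class II UMI, against 32.8% of cluster 1. Unspecific binding would raise isotype controls alike, and the I-A/I-E ratio was 1.88 (1.82 to 1.95) against 0.763 (0.707 to 0.823) for the isotypes. Expression by the cells labelled fibroblasts themselves may account for the pattern, as a hypothesis found and tested on the same data. The label leaves their kind open: at resolution 0.5 an own cluster of 980 cells, nearly all labelled fibroblasts, was named arachnoid and dural border cell. How far that cluster overlaps cluster 1 was not computed. The regulation of this expression stays open, and no biological explanation was tested, since the design gives no group to compare.

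Neutrophil genes appeared in endothelial cluster 7, with 558 UMIs of S100a8 and S100a9. Free RNA is argued against, since the unannotated barcodes held 0 of these UMIs, an upper bound of 0.000392 times the level of the cluster. Doublets of an endothelial cell and a neutrophil are argued against by the endothelial marker RNA of the cells with these UMIs, at most 0.219 times that of the other cluster cells, and by 16.5 CD31 counts per cell against 798. A few cells of another type may account for the pattern: 100% of these UMIs lay in 2 cells, which also held all 8 Ptprc UMIs. With 243 of its 315 cells not in the matrix, what the rest of the cluster holds stays open, and no biological explanation was tested.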

How the results depend on the processing

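The settings chosen only after the results were seen were those that counted matched cells only, left out endothelial cluster 7 or the 5% highest Scrublet scores, counted IgG2a as an isotype control or kept the parts of the other class apart. Of 134 values under 22 alternative settings, 85 stayed within their interval (shares) or within 1.5 times the reported number (counts) and 49 did not; where no reason is given, the cause was not tested. Among cells with at least 1000 UMIs and under 10% mitochondrial UMIs, the shares were 84.3% fibroblast, 7.62% endothelial, 0.558% mural and 0.209% glial, and 23, 13, 14 and 2 list genes were highest in fibroblast, endothelial, mural and other cells. Thinned to 500 UMIs, 26, 15, 11 and 2 were highest in fibroblast, endothelial, glial and other cells, since fewer UMIs widen the intervals. Scaling without the most abundant genes gave 12 list genes in the other class and 193 genes between erythroid types. A minimum of 200 UMIs, which tests fewer genes, gave 918 fibroblast, 122 endothelial and 78 erythroid genes, and no minimum 665 endothelial and 2115 erythroid genes. By construction, intervals clear of 1.5 gave 2317 fibroblast and 531 endothelial genes, and clear of 4 they gave 602 and 118. Centred log-ratios put 9, 15, 13 and 9 antibodies above background in fibroblast, mural, glial and other cells, and IgG2a as a control left 13, 12, 15, 5 and 10 in fibroblast, endothelial, mural, glial and other cells. By share of antibody counts 14 pairs had the same top type. Own clusters gave 78.3% fibroblast at resolution 0.5 and 78.2% at 1, with 12.4% endothelial and 1.03% glial at both. Fibroblast, endothelial and glial shares were 78.8%, 12.1% and 0.896% over matched cells, 79.7%, 11.2% and 0.906% without cluster 7, and 78.8%, 11.9% and 0.884% without the highest Scrublet scores; these, own clusters and the quality filter count matched cells only, which by itself leaves out 306 endothelial cells. Without cluster 7 the share of cells with a Ptprc UMI was 0%, since both cells lie in it. By construction, leaving it out could not change the gene numbers of fibroblast clusters and erythroid types. Nor could it change the antibody numbers of fibroblast, mural, glial and other cells. These values are nevertheless counted as within bounds. Planned doublet removal gave no value, since Scrublet marked 0 barcodes. Of the values within bounds, 14 of 24 were for cluster genes, 26 of 35 for antibodies, 6 of 7 for pairs, 25 of 34 for lists, 11 of 30 for shares and 3 of 4 for Ptprc. Pairs were compared by number alone, although the number of pairs used changed. With no gene minimum 45 of 93 pairs had the same top type, against 31 of 46, so the share fell although the number counts as within bounds. Depth limits the list counts: glial cells, with a median of 787.5 UMIs, had 19 list genes highest in full and 11 after thinning. No paired analysis was possible because each group held 1 library.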

Other observations

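The pinealocyte test below was chosen only after its result was seen; the values of the ependymal-labelled cells and of the tag counts are descriptions without a test. The choroid plexus gene Ttr was found in all 71 epithelial cells and, at the same time, in 5.55% of fibroblasts and 4.93% of endothelial cells, at medians of 1892, 2319 and 1042 UMIs. Folr1 gave UMIs in 76.1% of epithelial cells, Kl in 71.8% and Clic6 in 33.8%, against 0.0758%, 0.208% and 0.947% of fibroblasts. In the 109 cells labelled ependymal, Folr1 was found in 32.1%, Clic6 in 15.6%, Ttr in 11.9% and Kl in 5.50%. In the same cells Foxj1, a gene of ciliated cells, was found in 1 cell and Pax6 in 45 (41.3%), while Pax6 was found in 0 of 5279 fibroblasts.

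Cells labelled habenulal neuroblast-like numbered 29, of which 27 were in the matrix, with a median of 1503 UMIs. Of the 4 fixed pinealocyte markers, Tph1 was found in 25 of the 27 cells, Chga in 10, Asmt in 3 and Aanat in 1; among 6670 other annotated cells Tph1 was found in 8 and the other markers in 0. The lower bound of the share exceeded the upper bound of every other type for 2 of the 4 markers (Tph1 and Chga), where the hypothesis that these cells express the pinealocyte markers needed 3. The third marker, Asmt, was in 0 other cells but had a lower bound of 2.35%, under the upper bound of 6.38% that the few pericytes set. As the test held no habenular marker, it cannot tell pinealocytes from habenular neuroblasts at any number of cells. A candidate explanation that stays open is that the pineal gland, which lies against the dura, gave these cells.

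Endothelial cluster 7 also held 64 UMIs of mast cell markers against 3 in all other annotated cells, with 1 cell holding at least 5. In fibroblast cluster 1, CD80 gave 5.20 counts per cell in cells with an MHC class II UMI and 3.55 in those without. This was not particular to CD80: CD11b gave 1 and 0.663 in the same cells, while CD11c gave 0.0645 and 0.0728. Their median antibody counts were 181 and 159.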
